A study of Homo sapiens with 92 samples.

How the data were processed

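Gene expression was read from 23 RNA libraries of human WI-38 fibroblasts, one file per library, and histone marks from peak lists of H3K4me3, H3K9me3 and H3K27me3 at OIS days 0, 2, 6 and 10 and in proliferative and senescent RS cells. Hi-C and bisulfite files were not analysed here. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a stranded kit. The submitters' processing notes name STAR 2.5.0b, DESeq2, Bowtie2, SAMtools, MACS2, SICER, Trim Galore and the builds hg19 and GRCh37. The role and order of these tools, the annotation and the counting step are not given in the sources used here.

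Gene values are FPKM as deposited by the authors, per the file headers, scaled to gene length and to a depth factor whose kind is not given in the sources used here. Each FPKM value was a whole multiple of one read's worth in its library, so whole reads could be recovered for 37750 of 37750 genes with a value above 0, at a tolerance of 1e-06. The recovered factors followed median-ratio size factors rather than library totals. The recovered libraries held 40190921 to 107939616 reads in genes, the fewest in RS proliferative and the most in OIS day 2. Over 19 replicate pairs the chi-square per gene with at least 20 reads ran from 5.37 to 189 and the lowest correlation was 0.990, so replicates varied more than read sampling alone.

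Peak files carry no header line, and their layout was read from the values. In the H3K9me3 and H3K27me3 files the deposited counts are whole numbers of reads per island in the immunoprecipitated and control libraries. The deposited fold in these files is the caller's ratio of immunoprecipitated to control reads, and the deposited FDR is the caller's adjusted p-value. Islands are built of 10 kb windows and are unfiltered, with some above an FDR of 0.05. In the H3K4me3 files the deposited score, fold over background and -log10 of the adjusted p are as the authors' peak caller wrote them. The labels of both replicates of a condition name the same list, and whether reads were pooled before calling is not given in the sources used here. Peak folds and scores served only to pick the stricter 0.5 of each list.

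The design assumed read counts. Because the files hold FPKM, limma 3.58.1 with an intensity trend was run on log2(FPKM+1) in R 4.3.3, and the count-based tools were run on the recovered reads as alternatives with edgeR 4.0.16 and DESeq2 1.42.0. Genes with a group mean of at least 0.5 FPKM in any group of the fit were tested. Changes on the log2(FPKM+1) scale understate folds, most of all for genes near or below 1 FPKM. The limit of at least 2-fold on calls was set on FPKM+1. The 13 OIS libraries shared one fit, the RS libraries another and the siRNA libraries one of their own, and the difference between OIS day 10 and RS was fitted as an interaction over 11 libraries. Adjusted p-values are Benjamini-Hochberg values, called at 0.05. Of 38108 gene rows, 895 carry a name that occurs more than once (144 names) and were left out of the tests.

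Fixed gene lists, 27 in number, were tested with camera from limma on log2(FPKM+1) at a preset correlation of 0.01, with at least 3 tested members, and again with an estimated correlation. Of 663 list genes 649 were found, 5 of them under another symbol. Adjustment ran over the lists of each comparison. Named genes were fixed genes and, for the 4 main comparisons, the 8 largest rises and falls with a mean log2(FPKM+1) of at least 2, which stood in for a mean log2 CPM, and non-overlapping libraries. Up to 4 further members were named per list. Histone genes belong to a multigene family, so the split of reads among them is uncertain.

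Peak overlap of at least 1 bp was counted, and shared length was set beside 1000 circular shifts of one list along each chromosome. A comparison of promoter peaks with expression was not run, because no hg19 gene coordinates were at hand. The gene lists, named-gene rule, comparisons and alternatives from the design were fixed before the data were examined.

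The limma fit and the list test were tested on simulated data for 4 comparisons. In each, 67 genes were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. With 14370 simulated genes for OIS day 10 the recovered shares were 88.1% at 1.5-fold, 100% at 2-fold and 98.5% at 4-fold, with 20 false calls. For RS (13867 genes) they were 11.9%, 79.1% and 100% with 11 false calls, and for siDNMT1 (13927 genes) 74.6%, 100% and 98.5% with 12 false calls. For the difference between OIS day 10 and RS (14600 genes) they were 5.97%, 35.8% and 86.4% with 4 false calls. The 20 false calls for OIS day 10 stand beside 59, 67 and 65 recovered genes, and the 11 for RS beside 8, 53 and 66. Far fewer genes were changed than are called in the data, so the share of false calls there was not measured. Camera was run on a list of raised genes and a list of unchanged genes per comparison. Its p was at most 4.75e-53 for the raised lists and 0.127 to 0.585 for the unchanged lists. Genes were simulated independently of each other, so the list test was not tried on correlated genes. The other OIS days share the fit of day 10 and were not simulated on their own, nor were the correlations, the count-based tools and the read recovery. The peak overlap step was right in 50 of 50 simulated sets. Tables and figures were made with data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.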

Results

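Human fetal lung fibroblasts of the WI-38 line were profiled in 92 samples, of which 48 came from chromatin immunoprecipitation, 23 from RNA, 17 from Hi-C and 4 from whole-genome bisulfite sequencing. Gene expression and histone peak lists were analysed, and the Hi-C and bisulfite files were not analysed here. Oncogene-induced senescence (OIS) was followed in WI-38hTERT/GFP-RAF1-ER cells, which carry a RAF1 fusion that is switched on by tamoxifen. RNA came from day 0 (n = 3) and from days 2 (n = 3), 4 (n = 3), 6 (n = 2) and 10 (n = 2) of 20 nM 4-hydroxytamoxifen. Replicative senescence (RS) was read in primary WI-38 cells, proliferative (n = 3) and senescent (n = 3). At OIS day 5 an siRNA against DNMT1 (siDNMT1, n = 2) was set against the control siRNA labelled siNT4 (n = 2). Levels are FPKM as mean ± SD, and changes are log2 differences on the log2(FPKM+1) scale with adjusted p from limma. Counts of changes of at least 2-fold refer to FPKM+1, so some genes whose FPKM changed 2-fold are left out.

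The uninduced cells differed from the induced cells in the make-up of their libraries. RN7SL1, the RNA of the signal recognition particle, took 23.7 to 25.6% of the reads at day 0, 6.36 to 7.69% at day 2 and 0.885 to 0.934% at day 10. In the primary cells it took 25.1 to 25.9% when proliferative and 20.1 to 24.0% when senescent. With siDNMT1 it took 6.10 and 6.49%, and with siNT4 5.40 and 6.01%. Of 216 tested small RNA genes, 180 fell and 7 rose at day 10 against day 0 (median -1.76), while their median was 0.12 at day 10 against day 2. Induction goes with this library difference in the change from day 0 to day 2. Days 2 and 4 were alike in RN7SL1, at 6.13 to 6.88% at day 4, and in small RNA medians of -1.85 and -1.99 against day 0. They differed in the small RNA RN7SK, which took 2.96 to 3.22% of the reads at day 4 and less at day 2. IL1B stood at 8.66 ± 0.0655 and 1173 ± 130.0 FPKM at days 2 and 4 (n = 3 each). That rise does not go with RN7SL1 or the small RNA medians. The change from day 2 to day 10 also goes with a difference in make-up. RN7SL1 fell again, and the small RNA RN7SK took 1.85 to 1.93% of the reads at day 2 and 5.71 to 5.86% at day 10. The labels do not say that replicates are separate cultures, so the p-values may measure technical spread only.

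**Figure D1:**
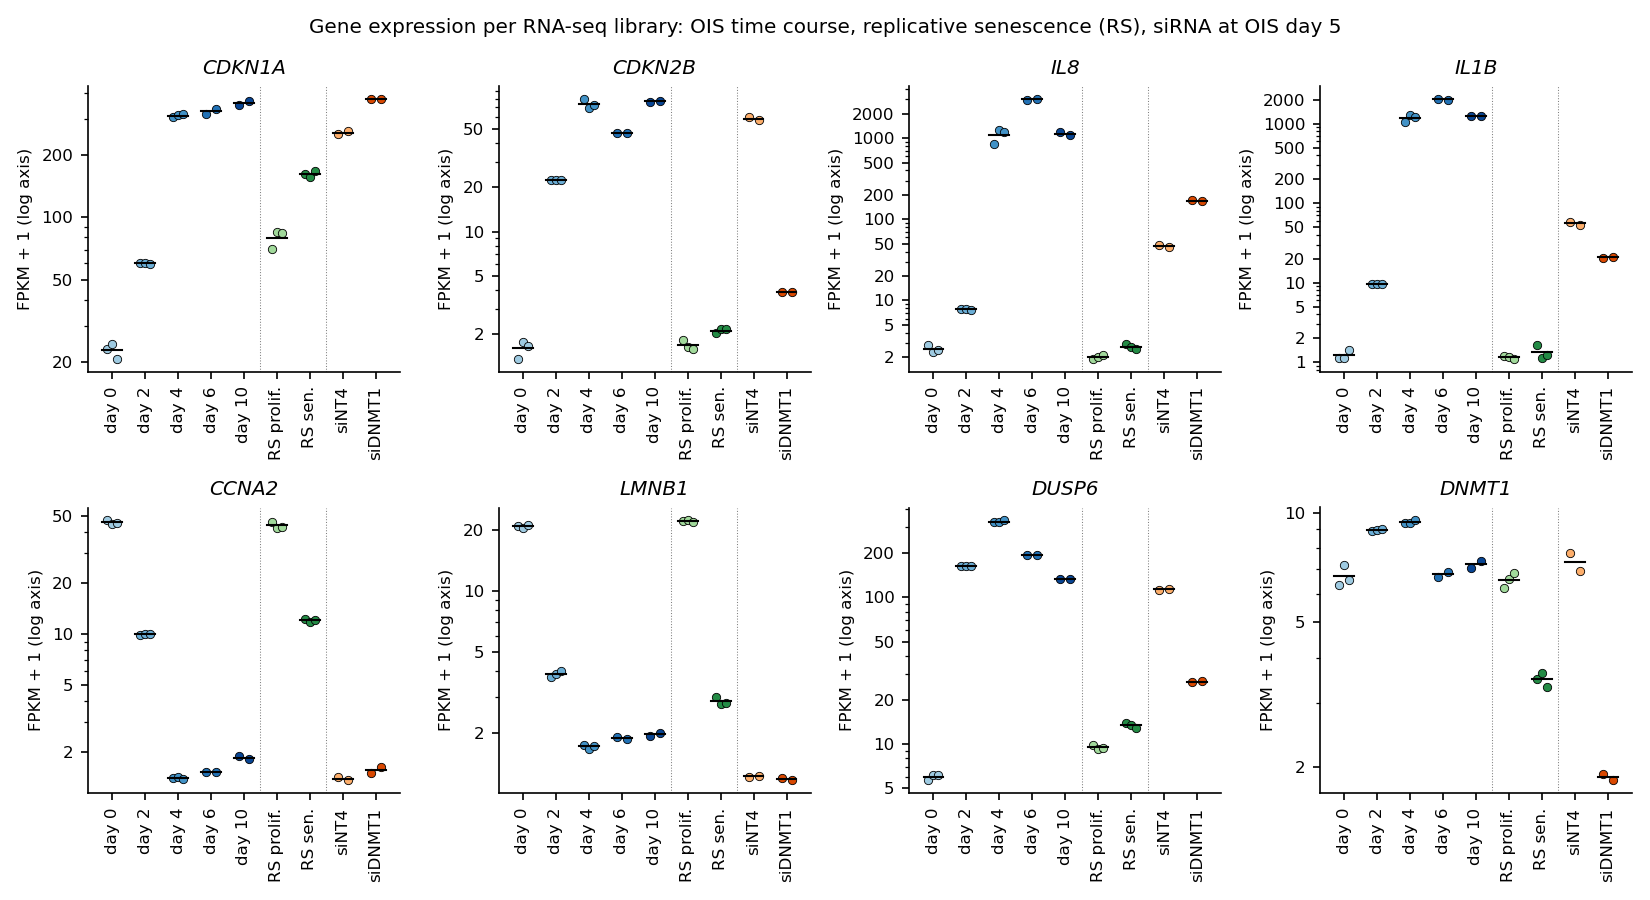
FPKM + 1 of CDKN1A, CDKN2B, IL8, IL1B, CCNA2, LMNB1, DUSP6 and DNMT1 in each RNA library on a log axis, with a bar at each group mean. Groups hold 2 or 3 libraries.

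By day 2 DUSP6, SPRY2 and SPRY4 had risen, while IL6 and CCL2 had fallen. DUSP6, a phosphatase made as feedback on ERK, rose from 5.00 ± 0.276 (n = 3) to 163.1 ± 0.112 (n = 3) FPKM, a log2 change of 4.78 (limma adjusted p = 2.2e-15). SPRY2 (3.97) and SPRY4 (4.07), Sprouty inhibitors of receptor signalling, also rose, as did the collagenase gene MMP1 (7.29) and the ligand gene AREG (7.14), whose reads are shared with its near copy AREGB. HMGA1, a chromatin architecture gene, rose by 3.45 and HMGA2 by 1.78. LMNB1, the lamin B1 gene whose loss marks senescent nuclei, had already fallen from 19.8 ± 0.446 to 2.90 ± 0.137 FPKM (-2.42). IL6 (-2.55), which encodes a cytokine, and CCL2 (-3.83), which encodes a monocyte attractant, fell at this time. IL1B rose by 2.99 and IL8 by 1.63, to 8.66 ± 0.0655 and 6.81 ± 0.0918 FPKM.

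At day 2, 13076 of 16064 tested genes changed, 6565 up and 6511 down, and 2948 of them by at least 2-fold. ERK targets rose in 21 of 22 genes (median 2.17, camera adjusted p = 1.8e-08), with adjusted p = 0.0514 with an estimated correlation. Proteases and matrix regulators of the senescence-associated secretory phenotype (SASP) rose in 19 of 21 (camera adjusted p = 3.9e-06, and 0.147 with an estimated correlation). Mitosis genes fell in 27 of 28 (median -1.33, camera adjusted p = 9.5e-10, and 0.00798 with an estimated correlation) and DNA replication genes in 32 of 34 (median -1.24, adjusted p = 3.0e-10, and 0.00798 with an estimated correlation). Histone genes fell in 49 of 53 (camera adjusted p = 2.8e-12, and 0.147 with an estimated correlation). SASP cytokine genes split into 9 up and 5 down of 24 (camera adjusted p = 0.518). Contractile genes fell in 8 of 10 (camera adjusted p = 0.0201, and 0.501 with an estimated correlation), and lysosome genes rose in 16 of 24 (adjusted p = 0.0118, and 0.501 with an estimated correlation). Ribosomal protein genes fell in 30 of 43 (median -0.55, camera adjusted p = 0.000257, and 0.266 with an estimated correlation), a direction that turned to 0.17 with scaling to total reads.

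IL1B, IL8 and MMP3 rose steeply by day 4 and had their highest mean of the time course at day 6. IL1B, an inflammatory cytokine gene at the top of the SASP, reached 1173 ± 130.0 FPKM at day 4 (n = 3, log2 change 9.91) and 2020 ± 26.9 at day 6 (n = 2, 10.70). IL8 (also CXCL8), a neutrophil attractant, reached 1097 ± 216.2 at day 4 (8.75) and 3008 ± 38.5 at day 6 (10.22), and MMP3, the stromelysin gene, 653.3 ± 188.2 (7.69) and 2552 ± 17.4 (9.70). IL6 rose by 2.27 at day 4 and 2.57 at day 6. CDKN1A, the p53-driven cell cycle inhibitor p21, rose by 3.77 and 3.84, and CDKN2B, which encodes p15, by 5.53 and 4.88. Cyclin A2 (CCNA2) fell by 5.03 and 4.91. DNMT1, the maintenance DNA methyltransferase, rose slightly at day 4 (0.49, to 8.43 ± 0.0824 FPKM) and did not pass at day 6 (0.02, limma adjusted p = 0.71), where it passed with scaling to total reads (0.81), by TMM factors (0.13) or without day 0 replicate 2 (0.0715).

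IFIT1, IFI6 and IFI27 rose at day 4, and IFIT1 fell below day 0 by day 10. IFIT1, an interferon-induced RNA sensor gene, rose from 6.19 ± 0.247 FPKM at day 0 to 104.2 ± 10.1 at day 4 (3.87), stood at 9.09 ± 0.246 at day 6 (0.49) and fell to 0.408 ± 0.0375 at day 10 (-2.35). IFI6 and IFI27, further interferon targets, rose at day 4 by 3.60 and 3.17 and fell at day 10 by 0.98 and 0.26. The fall of IFI27 is smaller than the move of the median of all genes with scaling to total reads (0.03 to 0.80). All 34 tested genes of this list rose at day 4 (median 2.91, camera adjusted p = 1.1e-10, and 0.194 with an estimated correlation), against 25 at day 6 (median 0.89, adjusted p = 0.00172, and 0.451 with an estimated correlation). At day 10 the list held 14 risen, 13 fallen and 7 not past (median -0.05, camera adjusted p = 0.725), and its median turned to 0.43 with scaling to total reads. At day 2 it held 7 risen and 18 fallen (camera adjusted p = 0.101), and it passed with scaling to total reads (adjusted p = 0.00301).

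At day 4 against day 0, 14114 genes changed, 7441 up and 6673 down, and at day 6 13910, 7171 up and 6739 down. SASP cytokine genes rose in 20 of 24 at day 4 (median 3.42, camera adjusted p = 0.000231, and 0.218 with an estimated correlation) and in 21 at day 6 (median 4.78, adjusted p = 8.5e-05, and 0.238 with an estimated correlation). ERK targets rose in 19 of 22 at both days (medians 2.43 and 1.91, camera adjusted p = 7.2e-06 and 9.1e-06, and 0.112 and 0.0902 with an estimated correlation). p53 targets rose in 24 of 27 at day 4 (camera adjusted p = 0.00038, and 0.126 with an estimated correlation) and in 21 at day 6 (adjusted p = 0.00157, and 0.163 with an estimated correlation). All 28 mitosis genes fell at day 4 (median -3.76, camera adjusted p = 3.0e-13, and 0.00436 with an estimated correlation), among them MKI67 (-2.65), a marker of cycling cells. NF-kB feedback genes rose in 14 of 16 at day 4 (camera adjusted p = 0.000425, and 0.194 with an estimated correlation). Ribosomal protein genes fell in 34 of 43 at day 4 (camera adjusted p = 6.4e-07, and 0.112 with an estimated correlation) and in 41 at day 6 (adjusted p = 4.5e-13, and 0.0313 with an estimated correlation).

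By day 10 CDKN1A, CDKN2B and CDKN2A and the interleukin 1 genes were up, and LMNB1 and HMGB2 were down. CDKN1A rose from 21.8 ± 1.84 (n = 3) to 355 ± 11.8 (n = 2) FPKM (3.97, SE 0.0569, limma adjusted p = 1.3e-13), CDKN2B from 0.606 ± 0.214 to 75.8 ± 0.854 (5.59) and CDKN2A, the p16 and ARF gene, from 0.904 ± 0.118 to 8.25 ± 0.652 (2.28). IL1B (10.00, SE 0.101), IL8 (8.82), IL1A (7.51) and MMP3 (8.47) rose, and IL6 rose by 0.61 (limma adjusted p = 0.0179). The call for IL6 was lost without day 0 replicate 3 (adjusted p = 0.057), day 10 replicate 1 (0.0706) or day 10 replicate 2 (0.0639) and with a pseudocount of 10 (0.103). CCL2 fell by 3.07. Among the 8 largest rises were further CST1 (10.84), a secreted cystatin, the TNF family cytokine TNFSF15 (8.09), the granulocyte growth factor CSF3 (7.47) and CST4 (7.11), whose reads may be shared with CST1. The largest falls lay in replication-dependent histone genes, with HIST1H4C (-7.76), HIST1H4D (-7.65) and HIST1H2BI (-6.86), and in SNHG3 (-6.83), which hosts small nucleolar RNAs. LMNB1 (-3.40) and HMGB2 (-4.35), a chromatin gene lost on senescence entry, fell, and HMGA1 (1.43) and HMGA2 (0.83) rose.

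Genes of the methylation and silencing machinery moved apart at day 10. DNMT1 went from 5.70 ± 0.443 to 6.22 ± 0.234 FPKM, a rise of 0.11 that passed narrowly (limma adjusted p = 0.0444). The call was lost without day 0 replicate 1 (adjusted p = 0.142), day 0 replicate 3 (0.105) or day 10 replicate 2 (0.251), with no filter on low values (0.0688) and with all 23 libraries in one fit (0.095). Its partner gene UHRF1, which guides DNMT1 to replicated DNA, fell from 10.6 ± 1.33 to 1.72 ± 0.00516 (-2.09), and the remodeller HELLS fell by 1.88. DNMT3A (0.82), a de novo methyltransferase, and TET3 (1.24), a demethylation enzyme, rose, and DNMT3B fell by 0.99. EZH2, the Polycomb methyltransferase, fell by 1.71, while its cofactor JARID2 rose by 2.14 and the H3K9 demethylase KDM4B by 1.71. The DNA methylation list as a whole held 11 risen and 6 fallen of 18 (camera adjusted p = 0.323), the H3K9 methylation list 11 and 5 of 16 (adjusted p = 0.0628) and the Polycomb list 19 and 6 of 31 (adjusted p = 0.0736), and the last pair passed with scaling to total reads (0.0411 and 0.025). The HMG, HP1, macroH2A and lamina list fell in 20 of 30 genes (median -0.69, camera adjusted p = 0.0131, and 0.195 with an estimated correlation), but its median turned to 0.11 with scaling to total reads. CTCF, cohesin and condensin genes held 9 risen and 10 fallen of 22 (median -0.10, camera adjusted p = 0.283), a median that turned to 0.94 with scaling to total reads.

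At day 10, 13932 of 16064 tested genes changed, 7186 up and 6746 down, and 4910 by at least 2-fold. Counts adjusted over each list alone equalled those adjusted over all genes in every list at this day. All 53 histone genes fell (median -4.37, camera adjusted p = 1.1e-16, and 0.0903 with an estimated correlation). All 28 mitosis genes fell (median -3.54, camera adjusted p = 1.1e-12, and 0.00626 with an estimated correlation), such as the spindle assembly gene DLGAP5 (-4.82) and the spindle midzone gene PRC1 (-4.48). DNA replication genes fell in 32 of 34 (median -2.07, camera adjusted p = 1.3e-09, and 0.00626 with an estimated correlation), with TK1 (-4.71) and RRM2 (-2.83), which supply nucleotides. All 43 ribosomal protein genes fell (median -2.08, camera adjusted p = 3.2e-13, and 0.0302 with an estimated correlation), among them RPLP0 (-1.92), RPS23 (-3.06) and RPL32 (-2.51). The median of the ribosomal list was -0.87 with scaling to total reads. All 10 contractile genes fell (median -3.37, camera adjusted p = 4.6e-05, and 0.152 with an estimated correlation), among them TAGLN (-5.32), ACTA2 (-3.61) and TPM1 (-3.14), which build smooth muscle fibres. Collagen and matrix genes fell in 16 of 23 (median -1.06, camera adjusted p = 0.0135, and 0.435 with an estimated correlation), with DCN (-5.50) and COL3A1 (-3.91). With scaling to total reads the median of this list was -0.04.

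SASP cytokine genes rose in 20 of 24 (median 2.19, camera adjusted p = 0.000352, and 0.285 with an estimated correlation) and SASP proteases in 17 of 21 (median 2.23, adjusted p = 0.000656, and 0.176 with an estimated correlation), with MMP14 (3.71) and the urokinase gene PLAU (4.04). The SASP cytokine call was lost with scaling to total reads (adjusted p = 0.1). ERK targets rose in 18 of 22 (median 1.88, camera adjusted p = 0.000126, and 0.137 with an estimated correlation), DUSP6 by 4.48 and the phosphatase gene DUSP4 by 6.14. p53 targets rose in 24 of 27 (median 1.26, camera adjusted p = 5.1e-05, and 0.0903 with an estimated correlation), with PLK3 (3.50) and TP53INP1 (2.38), while TP53 itself fell by 0.81, a direction that turned with scaling to total reads. NF-kB feedback genes rose in 13 of 16 (median 1.25, camera adjusted p = 0.00835, and 0.285 with an estimated correlation), with NFKBIA (3.15) and ICAM1 (2.89), and the call was lost with scaling to total reads (adjusted p = 0.0519). SASP growth factor genes held 14 risen and 13 fallen of 29 (camera adjusted p = 0.543), with STC1 (6.00) and EREG (6.68) up. Lysosome genes rose in 14 of 24 (camera adjusted p = 0.0628), cholesterol synthesis genes in 14 of 21 (adjusted p = 0.0648) and mitochondrially encoded genes in 11 of 13 (adjusted p = 0.0628). With scaling to total reads the lysosome list (adjusted p = 0.00509) and the cholesterol list (0.014) passed. Cell cycle inhibitors held 7 risen and 6 fallen of 14 (camera adjusted p = 0.802), and CDKN2C fell by 3.13.

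Between days 2 and 10, inside the induced libraries, IL1B rose by 7.01, IL8 by 7.19, IL6 by 3.15 and MMP3 by 6.96, and NFKBIA, the inhibitor induced by NF-kB, rose by 4.32. CDKN1A rose by 2.57 and CDKN2B by 1.78. SPRY2 (-1.39) and HMGA1 (-2.02) fell, and DUSP6 fell by 0.30, a direction that turned to 0.20 with scaling to total reads. INSIG1, which restrains sterol synthesis, rose by 3.23, and FDFT1 (1.17) and SQLE (0.99), enzymes of cholesterol synthesis, also rose. UHRF1 fell by 1.42, and DNMT1 fell by 0.31, which turned to 0.13 with scaling to total reads. RAF1, whose reads include the introduced fusion, rose by 1.28 from day 2 to day 10.

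In this late comparison 12567 genes changed, 6154 up and 6413 down. All 28 mitosis genes fell (median -2.48, camera adjusted p = 1.3e-13, and 0.00498 with an estimated correlation) and DNA replication genes fell in 27 of 34 (33 past when adjusted over the list alone against 32, adjusted p = 2.4e-05, and 0.0314 with an estimated correlation). Histone genes fell in 52 of 53 (camera adjusted p = 5.5e-17, and 0.0578 with an estimated correlation). p53 targets rose in 23 of 27 (median 1.00, camera adjusted p = 9.5e-08, and 0.0314 with an estimated correlation). All 43 ribosomal protein genes fell (median -1.34, camera adjusted p = 3.8e-15, and 0.0304 with an estimated correlation). SASP cytokine genes rose in 19 of 24 (camera adjusted p = 8.3e-06, and 0.176 with an estimated correlation), NF-kB feedback genes in 15 of 16 (adjusted p = 8.3e-06, and 0.0807 with an estimated correlation) and cholesterol synthesis genes in 18 of 21 (adjusted p = 5.8e-05, and 0.0578 with an estimated correlation). ERK targets fell in 15 of 22 (median -0.38, camera adjusted p = 0.0304, and 0.263 with an estimated correlation), a direction that turned to 0.09 with scaling to total reads, where the call was lost (adjusted p = 0.211). Contractile genes fell in 9 of 10 (camera adjusted p = 0.000351, and 0.174 with an estimated correlation) and collagen genes in 18 of 23 (adjusted p = 0.000381, and 0.255 with an estimated correlation).

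**Figure D2:**
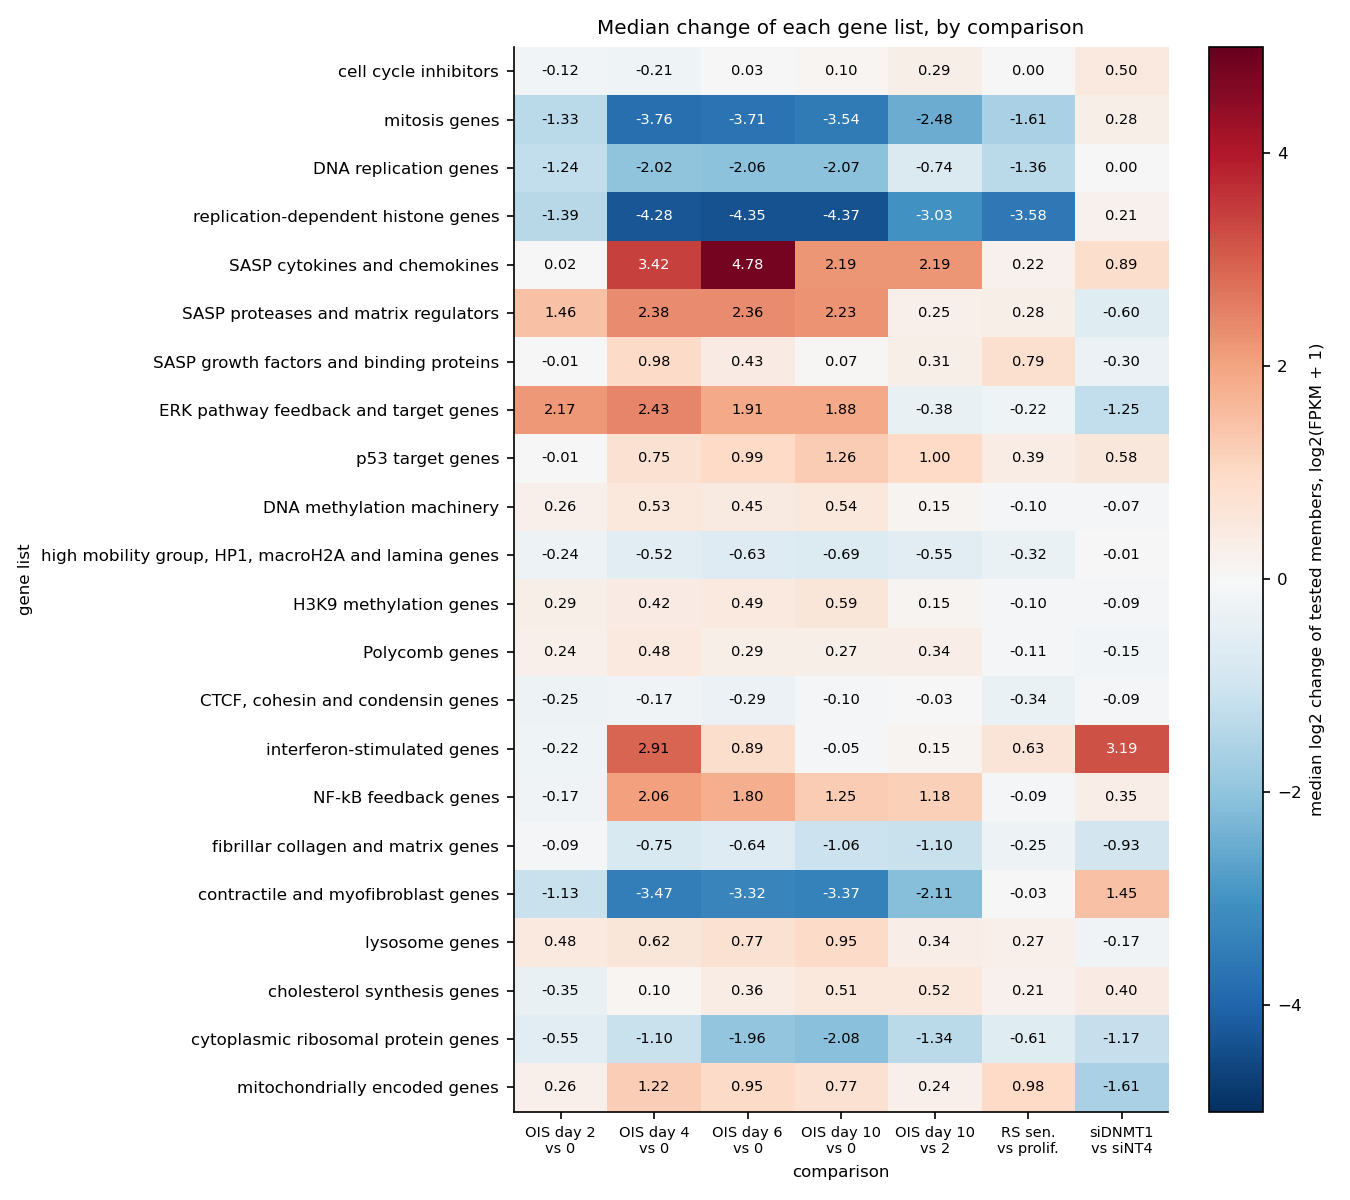
Median log2 change of the tested genes of each fixed list, other cell types left out, in 5 OIS time comparisons, in replicative senescence and with siDNMT1 at OIS day 5. Directions of several lists turn with scaling to total reads, among them the HMG, HP1, macroH2A and lamina list at day 10, which goes from -0.69 to 0.11.

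In replicatively senescent cells LMNB1, HMGB2 and CCNA2 (-1.87) fell and CDKN1A rose. LMNB1 fell from 21.1 ± 0.166 (n = 3) to 1.85 ± 0.117 (n = 3) FPKM (-2.96, limma adjusted p = 1.0e-05), and HMGB2 by 1.86. CDKN1A rose from 78.9 ± 8.24 to 161.5 ± 5.42 (1.03, SE 0.0920, limma adjusted p = 0.00025), CDKN2B by 0.33, and CDKN2A did not pass (0.10, adjusted p = 0.435). The largest rises lay in the interferon targets IFI27 (3.06, SE 0.146) and IFI6 (2.83), in WNT16 (2.65), a Wnt ligand gene made by senescent fibroblasts, which reached 115.4 ± 6.06 FPKM, and in MMP3 (2.62), PPP1R3C (2.60) and the cyclin gene CCND2 (2.45). The largest falls lay in histone genes, with HIST1H1B (-4.61), HIST1H3H (-4.50) and HIST1H2AJ (-4.48). IL8 (0.41), IL6 (0.33) and CCL2 (0.72) rose slightly, and IL1B stayed below the tested level at 0.321 ± 0.261 FPKM in senescent cells. The call for IL6 was lost without proliferative replicate 2 (limma adjusted p = 0.0511) or 3 (0.0832), without senescent replicate 1 (0.0839) or 2 (0.088), with no filter on low values (0.0564), with all 23 libraries in one fit (0.0802) and with scaling to total reads (0.0541). DNMT1 fell from 5.55 ± 0.319 to 2.49 ± 0.155 (-0.91, limma adjusted p = 0.000121), UHRF1 by 1.75, EZH2 by 1.67 and DNMT3B by 0.37, while DNMT3A did not pass (-0.05, adjusted p = 0.544). Secreted factor genes IGFBP5 (1.32), IGFBP7 (1.40), TNFRSF11B (2.10) and NRG1 (1.54) rose, and ELN (-2.07), the elastin gene, and IL11 (-1.95) fell.

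In RS 7574 of 14234 genes changed, 3723 up and 3851 down, and 956 by at least 2-fold. Histone genes fell in 52 of 53 (median -3.58, camera adjusted p = 1.3e-24, and 0.345 with an estimated correlation), DNA replication genes in 33 of 34 (median -1.36, adjusted p = 9.0e-18, and 0.0957 with an estimated correlation) and mitosis genes in 27 of 28 (median -1.61, adjusted p = 1.9e-14, and 0.0786 with an estimated correlation), with CDC45 (-2.02), ORC1 (-1.79) and BUB1 (-1.66). Ribosomal protein genes fell in 39 of 43 (40 past when adjusted over the list alone against 39, camera adjusted p = 8.3e-09, and 0.379 with an estimated correlation). Interferon-stimulated genes rose in 18 of 22 (median 0.63, 20 past when adjusted over the list alone against 19, camera adjusted p = 3.7e-07, and 0.0657 with an estimated correlation), with STAT1 (1.12) and TRIM22 (1.26). SASP growth factor genes rose in 19 of 27 (25 past when adjusted over the list alone against 24, camera adjusted p = 1.8e-05, and 0.0657 with an estimated correlation). The HMG, HP1, macroH2A and lamina list fell in 20 of 31 (median -0.32, camera adjusted p = 3.9e-05, and 0.0657 with an estimated correlation), with TMPO (-2.02) and LBR (-1.41), which anchor chromatin at the envelope. Mitochondrially encoded genes rose in 12 of 13 (median 0.98, camera adjusted p = 0.000161, and 0.409 with an estimated correlation), with MT-CYB at 1.44.

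In RS p53 targets rose in 15 of 27 (19 past when adjusted over the list alone against 18, camera adjusted p = 0.00212, and 0.293 with an estimated correlation), with BTG2 (1.10) and SPATA18 (1.28). Lysosome genes rose in 14 of 23 (camera adjusted p = 0.00489, and 0.409 with an estimated correlation), with FUCA1 (1.05), and cholesterol synthesis genes in 9 of 20 (adjusted p = 0.0488, and 0.379 with an estimated correlation), with MSMO1 (0.91), a call lost with scaling to total reads (adjusted p = 0.0654). SASP proteases rose in 11 of 20 (18 past when adjusted over the list alone against 16, camera adjusted p = 0.0175, and 0.424 with an estimated correlation), with SERPINE2 (1.89) and MMP10 (2.17). ERK targets fell in 11 of 21 (16 past when adjusted over the list alone against 15, camera adjusted p = 0.0443, and 0.409 with an estimated correlation), with SPHK1 (-1.86), and CTCF, cohesin and condensin genes in 11 of 22 (adjusted p = 0.0338, and 0.561 with an estimated correlation). SASP cytokine genes held 6 risen and 3 fallen of 12 (camera adjusted p = 0.329). DNA methylation genes held 0 risen and 6 fallen of 17 (camera adjusted p = 0.0977), H3K9 methylation genes 3 and 5 of 16 (7 past when adjusted over the list alone against 8, adjusted p = 0.418) and Polycomb genes 7 and 11 of 30 (adjusted p = 0.198). NF-kB feedback genes held 4 and 4 of 15, with a median of -0.09 against a mean of 0.07 (camera adjusted p = 0.926). Contractile genes held 3 and 3 of 10, with a median of -0.03 that turned to 0.08 with scaling to total reads and a mean of 0.10 (camera adjusted p = 0.926).

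The OIS and RS programs shared falling genes above the number if independent. LMNB1, HMGB2, CCNA2, UHRF1 and EZH2 fell in both, whereas WNT16 rose by 2.65 in RS and fell by 3.21 at OIS day 10. Over 13653 genes the changes at day 10 correlated weakly with those in RS (Pearson 0.162, Spearman 0.0554). Genes that fell in both numbered 2120 against 1783 if the calls were independent, and genes that rose in both 1359 against 1395. Among changes of at least 2-fold, 350 genes fell in both against 93.6 if independent, and 68 rose in both against 57.1, while 160 fell at day 10 and rose in RS against 81.2, and 34 rose at day 10 and fell in RS against 65.8. Without a size limit, 1319 genes rose at day 10 and fell in RS against 1511 if independent, and 1686 fell at day 10 and rose in RS against 1646. The changes in IL1B (difference 9.81), IL8 (8.41), CST1 (7.97) and GDF15 (6.71), a stress cytokine gene, were higher in OIS, and those in SNHG3 (-7.02), PPP1R3C (-6.93), IGFBP3 (-6.78) and F3 (-6.70), the tissue factor gene, were lower. UHRF1 (-0.34, limma adjusted p = 0.0536), EZH2 (-0.04, adjusted p = 0.716) and IL6 (0.27, adjusted p = 0.112) did not differ past the level. UHRF1 passed with DESeq2 (-0.43), with edgeR and RLE or TMM factors (-0.47 and -0.49), with all 23 libraries in one fit (adjusted p = 0.0164), with a pseudocount of 0.1 (0.0433) and without OIS day 0 replicate 1 (0.00896) or RS senescent replicate 1 (0.0375). With scaling to total reads UHRF1 and EZH2 turned to 0.40 and 0.43. IL6 passed with that scaling (1.32) and with a pseudocount of 10 (0.20).

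DNMT1 stood at 0.922 and 0.845 FPKM in the siDNMT1 libraries and at 6.77 and 5.90 in the siNT4 libraries of OIS day 5. It fell from 6.34 ± 0.612 (n = 2) to 0.883 ± 0.0548 (n = 2) FPKM (-1.96, SE 0.0695, limma adjusted p = 2.6e-05). The largest rises lay in interferon genes. CXCL11 rose from 0.451 ± 0.00727 to 195.3 ± 33.8 FPKM (7.07), CXCL10 from 4.46 ± 0.0887 to 598 ± 132.6 (6.76), BST2 from 1.03 ± 0.142 to 207.5 ± 7.13 (6.69) and RSAD2 from 2.40 ± 0.102 to 226.9 ± 15.1 (6.07). These encode T cell attracting chemokines, the virion tether tetherin and the antiviral enzyme viperin. IFIT1 (5.19), IFIT2 (5.58), GBP1 (4.92) and MX1 (4.91), antiviral effector genes, rose as well. The largest falls lay in TNFRSF10D (-5.35), a decoy TRAIL receptor, CBLN2 (-5.20), ENPP1 (-5.06), the collagen VI gene COL6A3 (-4.97) and AREG (-4.70). CDKN2B fell from 57.7 ± 1.54 to 2.89 ± 0.0287 (-3.92) and CDKN2A by 0.36, a call lost with scaling to total reads (-0.0980), while CDKN1A rose from 255.6 ± 5.10 to 371.9 ± 0.150 (0.54) and TP53 by 1.08. IL6 (4.04), CCL2 (4.18) and IL8 (1.87) rose, IL1A (-0.93) and IL1B (-1.43) fell, and MMP3 did not pass (0.14, limma adjusted p = 0.089). MMP3 passed with DESeq2 (0.18), with edgeR and RLE or TMM factors (0.18 and 0.19) and with scaling to total reads (0.46).

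RAF1 and TERT, whose reads include the introduced genes, fell with siDNMT1. RAF1 went from 163.8 ± 10.2 to 26.9 ± 0.0897 FPKM (-2.56, limma adjusted p = 9.6e-06) and TERT from 550.8 ± 131.3 to 54.3 ± 3.71 (-3.30, adjusted p = 7.1e-05). DUSP6 fell from 112.9 ± 0.894 to 25.6 ± 0.301 (-2.10), the Sprouty genes SPRY2 by 1.61 and SPRY4 by 2.35, and SPRED1, a RAS pathway brake, by 2.40. HMGA1 (-2.27) and HMGA2 (-3.42) fell, and HMGB2 rose by 1.19. TAGLN (2.53) and ACTA2 (2.70), both low by OIS day 10, rose, as did CYR61 (4.14) and CTGF (3.08), matricellular targets of mechanical signalling. MT-CO3, which encodes a respiratory subunit, fell from 1655 ± 97.0 to 235.8 ± 0.649 (-2.81). Mitochondrial genes took 0.538 and 0.547% of the reads with siDNMT1, and 0.977 and 1.07% with siNT4. UHRF1 fell by 1.57, DNMT3A by 0.35 and the HP1 gene CBX5 by 1.92. The proliferation gene CCNA2 did not pass (0.17, limma adjusted p = 0.0775). It passed with edgeR and RLE or TMM factors (0.56 and 0.57), with all 23 libraries in one fit (adjusted p = 0.00409), without siDNMT1 replicate 1 (0.0435) and with scaling to total reads (0.0169).

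**Figure D3:**
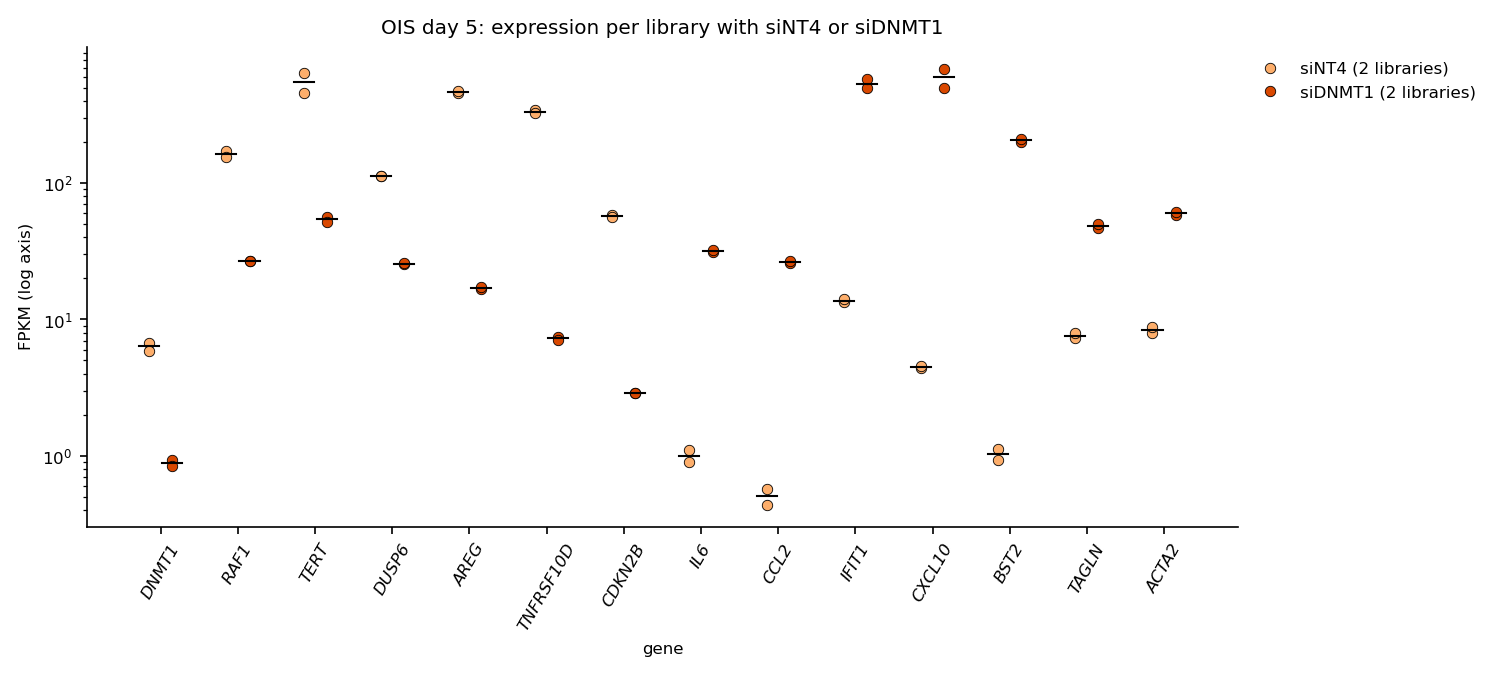
FPKM of 14 genes in each of the 2 siNT4 and 2 siDNMT1 libraries at OIS day 5 on a log axis, with a bar at each mean.

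With siDNMT1 10970 of 14438 genes changed, 4678 up and 6292 down, and 1837 by at least 2-fold. All 34 interferon-stimulated genes rose (median 3.19, camera adjusted p = 5.6e-17), with adjusted p = 0.524 with an estimated correlation. ERK targets fell in 20 of 22 (median -1.25, camera adjusted p = 4.1e-05, and 0.524 with an estimated correlation), p53 targets rose in 21 of 26 (26 past when adjusted over the list alone against 25, camera adjusted p = 4.1e-05, and 0.524 with an estimated correlation), with BTG2 (2.37), TP53I3 (1.62) and SESN1 (0.97), and SASP cytokine genes rose in 17 of 23 (median 0.89, adjusted p = 0.000213, and 0.524 with an estimated correlation). All 43 ribosomal protein genes fell (median -1.17, camera adjusted p = 5.0e-13, and 0.524 with an estimated correlation), as did all 13 mitochondrially encoded genes (median -1.61, adjusted p = 6.5e-05, and 0.658 with an estimated correlation). Contractile genes rose in 8 of 10 (median 1.45, camera adjusted p = 0.00254, and 0.524 with an estimated correlation), NF-kB feedback genes in 12 of 15 (adjusted p = 0.00345, and 0.524 with an estimated correlation) and histone genes in 24 of 51 (median 0.21, adjusted p = 0.0231, and 0.671 with an estimated correlation).

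Other lists did not pass with siDNMT1. SASP proteases held 5 risen and 13 fallen of 21 (camera adjusted p = 0.189), with PLAU (-2.78) and PLAT (-3.10), both plasminogen activators, down and SERPINE2 (2.14), their inhibitor, up. SASP growth factor genes held 11 and 15 of 27, with a median of -0.30 that turned to 0.02 with scaling to total reads against a mean of 0.07 (camera adjusted p = 0.894), STC1 (-2.82) and STC2 (3.82) moving apart. Collagen and matrix genes held 7 and 15 of 23 (camera adjusted p = 0.379), with FN1 (-2.52) down and THBS1 (2.08) up. DNA methylation genes held 6 and 7 of 16 (median -0.07, turning to 0.19 with scaling to total reads, camera adjusted p = 0.894). Polycomb genes held 11 and 16 of 30 (median -0.15, turning to 0.11 with scaling to total reads, camera adjusted p = 0.894), with PCGF5 up by 2.10. Mitosis genes held 6 and 1 of 11 (camera adjusted p = 0.0685), cholesterol synthesis genes 11 and 9 of 21 (21 past when adjusted over the list alone against 20, adjusted p = 0.426) and cell cycle inhibitors 7 and 4 of 12 (adjusted p = 0.222).

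The siDNMT1 changes ran against the OIS time course in most genes called in both, while IFIT1 rose in both. RAF1, whose reads include the introduced fusion, also fell with siDNMT1. The opposite changes therefore do not separate less DNMT1 from less of the fusion. IFIT1 rose by 3.87 at day 4 and by 5.19 with siDNMT1, whereas DUSP6 rose by 5.78 at day 4 and fell by 2.10 with siDNMT1, and TAGLN fell by 6.50 at day 4 and rose by 2.53. Over 13768 genes the siDNMT1 change correlated negatively with the change at day 4 (Pearson -0.288, Spearman -0.326) and day 6 (-0.273 and -0.274). Of genes that rose at day 4, 3872 fell with siDNMT1 against 3029 if independent, and 1475 rose in both against 2172. Among changes of at least 2-fold, 619 genes rose at day 4 and fell with siDNMT1 against 198.2 if independent, and 229 fell at day 4 and rose with siDNMT1 against 92.3. At that size 141 genes rose in both, above the 111.9 if independent, and 118 fell in both against 163.5. At day 6 those numbers were 3505 against 2839 for all changes and 564 against 180.8 for changes of at least 2-fold. CDKN1A rose at day 4, at day 6 and with siDNMT1.

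Most regions with H3K4me3, the active promoter mark, at OIS day 10 already carried it at day 0. Of the day 10 H3K4me3 peaks, 95.5% overlapped a day 0 peak, and the lists held 20584 peaks over 32.8 Mb at day 10 and 25153 over 45.4 Mb at day 0. H3K9me3, the mark of constitutive heterochromatin, covered 408.2 Mb in 1271 peaks at day 0, 864.6 Mb at day 2, 781.6 Mb at day 6 and 858.3 Mb in 2269 peaks at day 10. Of the day 10 H3K9me3 peaks 33.4% overlapped a day 0 peak, and 451.0 Mb were covered at day 10 only against 0.86 Mb at day 0 only. H3K27me3, the Polycomb mark, grew from 442.1 to 625.0 Mb, with 63.6% of day 10 peaks overlapping a day 0 peak. Shared length over joint length was 68.8%, 47.4% and 70.1% for H3K4me3, H3K9me3 and H3K27me3, against means of 0.743%, 10.2% and 9.84% over 1000 circular shifts. Each condition has 1 peak list, so spread between replicates is not measured.

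In RS both repressive marks covered more of the genome in senescent cells, with H3K9me3 both gained and lost. H3K9me3 went from 630.4 Mb in 1252 peaks to 857.9 Mb in 4528 peaks, and 40.9% of the senescent peaks overlapped a proliferative peak. Here 370.9 Mb were covered in senescent cells only and 143.4 Mb in proliferative cells only. H3K27me3 went from 520.8 to 775.1 Mb with 64.4% of peaks overlapping, and H3K4me3 from 24.8 to 44.2 Mb with 56.6% overlapping. H3K9me3 regions lay inside H3K27me3 regions over 1.46% of their length at OIS day 0, 3.53% at OIS day 10 and 4.18% in proliferative RS cells, each below the mean of the shifts (14.9%, 20.1% and 17.1%). In senescent RS cells the share was 44.4% against a mean of 26.3% over the shifts. The senescent RS lists and the OIS day 10 lists shared 70.8%, 45.9% and 68.6% of their joint length for H3K4me3, H3K9me3 and H3K27me3. The OIS day 0 and proliferative RS lists, neither of senescent cells, shared 53.8%, 51.1% and 70.0%. Of these, H3K9me3 covered 408.2 and 630.4 Mb and H3K4me3 45.4 and 24.8 Mb. Lists thus also differed without senescence. Depth and peak calling of the lists were not compared, so differences between lists need not come from senescence.

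**Figure D4:**
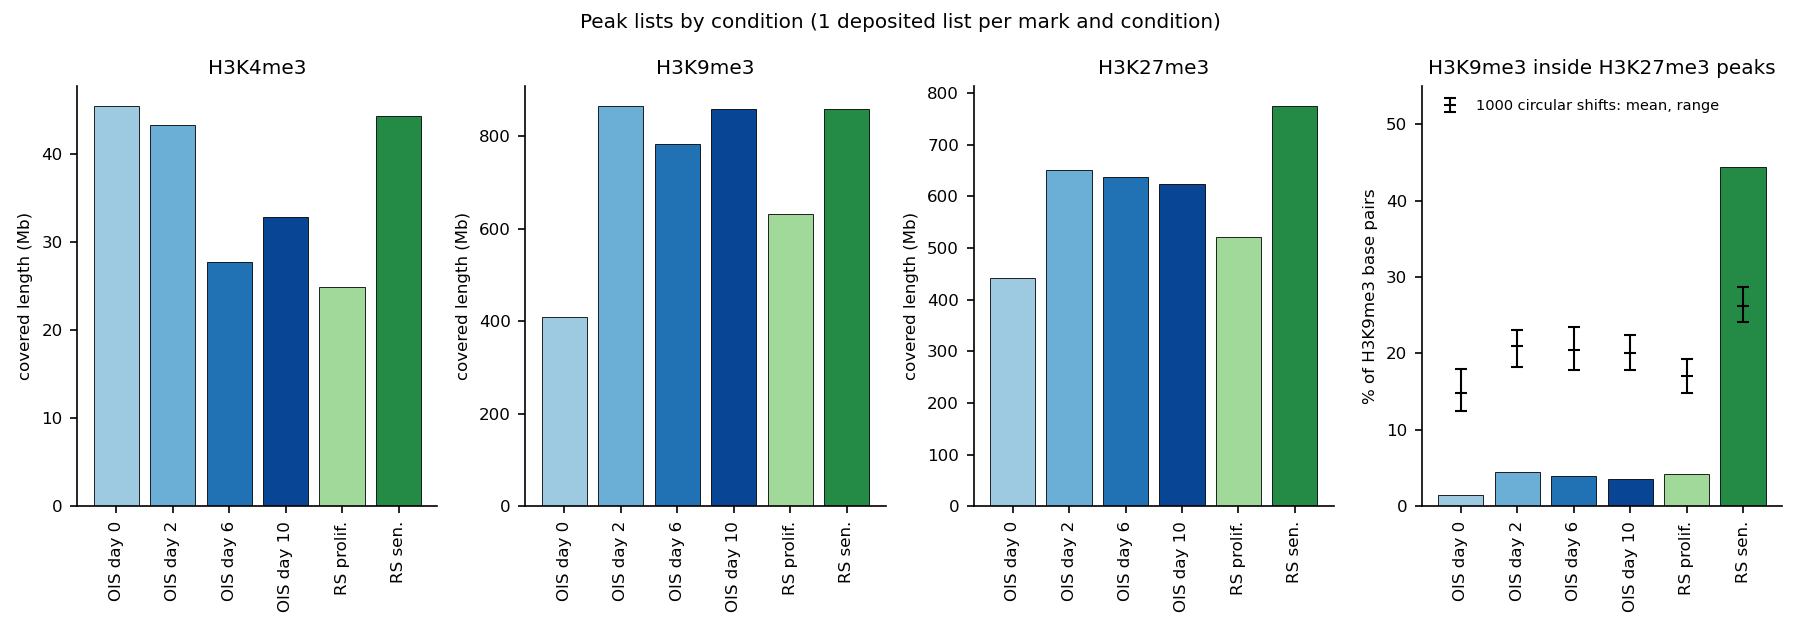
Covered length of H3K4me3, H3K9me3 and H3K27me3 peaks by condition, and the share of H3K9me3 length inside H3K27me3 regions beside the mean of 1000 circular shifts. In senescent RS cells the share was 44.4%.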

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

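Scaling to total reads was a test chosen after the results were seen. The difference between the OIS change (day 10 minus day 0, n = 2 and 3) and the RS change (senescent minus proliferative, n = 3 each) was tested as an interaction in limma, and 11944 of 16125 genes differed. Cell population goes with the kind of senescence, so these differences do not separate them. The day 0 libraries also differ from the day 10 libraries in their small RNA content (median -1.68 in this contrast). RN7SL1 took less of the reads at day 2 than at day 0, and less again at day 10. Changes before and after day 2 can therefore both go with the make-up of the libraries.

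The inhibitor genes CDKN1A, CDKN2A and CDKN2B rose more in OIS, as did IL1B, IL8, IL1A and MMP3, while the cell cycle inhibitor list did not pass (7 higher and 4 lower of 14, camera adjusted p = 0.508). CDKN1A differed by 2.94, CDKN2A by 2.18 and CDKN2B by 5.26. IL1B differed by 9.81, IL8 by 8.41, IL1A by 7.34 and MMP3 by 5.85, while CCL2, which rose slightly in RS and fell in OIS, differed by -3.80. DUSP6 differed by 3.99 and RAF1, with its introduced copy, by 2.72. TERT differed by 3.35 on FPKM, but its level in RS cells was near 0 and its direction turned in the count-based tools, to -1.18 with DESeq2. TP53 differed by -0.37, a direction that turned to 0.44 with scaling to total reads, and its call was lost without OIS day 10 replicate 1 (limma adjusted p = 0.136), OIS day 0 replicate 1 (0.0536) or 2 (0.0557) or RS senescent replicate 2 (0.056) and with no filter on low values (0.0505).

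MKI67, CCNA2 and some chromatin genes also differed singly, while the lists of HMG, HP1, macroH2A and lamina genes (camera adjusted p = 0.272), of DNA methylation genes (0.192) and of CTCF, cohesin and condensin genes (0.668) did not pass. MKI67 differed by -1.55, CCNA2 by -2.76 and HMGB2 by -2.48, and HMGA1 by 2.30 and HMGA2 by 1.08. DNMT1 (1.02) rose slightly in OIS and fell in RS, DNMT3A differed by 0.86 and DNMT3B by -0.61. LMNB1 differed by -0.45, which turned to 0.15 with scaling to total reads and did not pass with a pseudocount of 10 (-0.0502, limma adjusted p = 0.146).

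Of the 24 lists tested for this difference 13 passed with the preset correlation by camera in limma, and all 13 missed the level with an estimated one. Mitosis genes had a median difference of -2.30 (adjusted p = 0.0652 with an estimated correlation), SASP cytokine genes 2.14 (0.0652), ERK targets 2.26 (0.117) and ribosomal protein genes -1.47 (0.298). The ribosomal median was -0.36 with scaling to total reads. Contractile genes had -3.63 (adjusted p = 0.146 with an estimated correlation), NF-kB feedback genes 1.35 (0.143), p53 targets 0.66 (0.261), SASP proteases 1.86 (0.4, and a call lost at 0.0658 with scaling to total reads), Polycomb genes 0.43 (0.125) and H3K9 methylation genes 0.60 (0.143). Histone genes had -0.65 (adjusted p = 0.712 with an estimated correlation), DNA replication genes -0.44 (0.458) and interferon-stimulated genes -0.73 (0.266), and these medians turned to 0.15, 0.04 and 0.01 with scaling to total reads.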

How the results depend on the processing

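Scaling to total reads and by TMM, the edgeR run with TMM factors on recovered reads and the FDR limit on peaks were tests chosen after the results were seen. The other alternatives were planned. Of the alternative values for counts, correlations, overlaps and peak shares, 149 stayed within their limits and 28 moved. Over the 8 comparisons, 9344 named-gene values kept their call, 59 weakened, 23 strengthened and 25 turned direction. Of the list values 638 kept their call, 91 weakened and 11 strengthened.

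Asking for at least 2-fold left 2948 genes at OIS day 2, 4810 at day 4, 4805 at day 6, 4910 at day 10, 2570 at day 10 against day 2 (38.5% of them up against 49.0% of all calls), 956 in RS, 5279 for the difference between OIS and RS and 1837 with siDNMT1. Shared directions of OIS day 10 and RS went from 3479 genes to 418. The count-based tools gave more calls for each of the 8 comparisons, such as 17052 with DESeq2 at day 10. Of the list tests in the 4 main comparisons 48 passed, 3 with an estimated correlation, 48 with median-ratio factors and 49 with scaling to total reads.

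Scaling to total reads took the median change of all genes from 0.00288 to 0.39 at day 2, from 0.05 to 0.39 at day 4, from 0.03 to 0.58 at day 6, from 0.03 to 0.80 at day 10, from -0.00158 to 0.33 at day 10 against day 2, from -0.00458 to 0.73 for the difference, from -0.08 to 0.16 with siDNMT1 and from -0.02 to 0.05 in RS. The share of risen calls went from 50.2% to 77.9% at day 2, from 52.7% to 70.1% at day 4, from 51.6% to 75.2% at day 6, from 51.6% to 79.4% at day 10, from 49.0% to 71.1% at day 10 against day 2, from 50.5% to 79.0% for the difference, from 42.6% to 64.0% with siDNMT1 and from 49.2% to 58.0% in RS, where calls went from 7574 to 5762 genes. This scaling ended 6 list calls and added 11, such as collagen genes at day 4 (camera adjusted p = 0.0498), at day 6 (0.00996) and for the difference (0.0126). The collagen medians were then -0.12, 0.23 and 0.16, below the 0.39, 0.58 and 0.73 of all genes. At day 6 and for the difference the added calls thus go with a smaller rise than in other genes.

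Directions that turned with scaling to total reads were those of TP53 (0.11) and MAGEA12 (0.21) at day 10, TP53 at day 4 (0.0749), TP53 (0.28), DNMT1 (0.13) and DUSP6 (0.20) at day 10 against day 2, RAF1 in RS (0.0492), and, for the difference, UHRF1 (0.40), EZH2 (0.43), LMNB1 (0.15), TP53 (0.44), DHFR (0.0177), MAGEA12 (0.20) and SYT1 (0.28). For the difference, TERT turned to -1.18 with DESeq2, -1.15 with edgeR and RLE factors and -1.16 with edgeR and TMM factors, and KRT19 to 0.63, 0.46 and 0.44. EZH2, not past in the reported result, turned to 0.0169 with a pseudocount of 10, and ran from -0.0876 without RS proliferative replicate 1 to 0.0165 without RS proliferative replicate 2. Without 1 library DNMT1 at day 6 ran from -0.0191 to 0.0715, and TP53 at day 10 against day 2 from -0.184 to 0.0039. Total reads include small RNA reads, and RN7SL1 alone took 23.7 to 25.6% of them at day 0 and 0.885 to 0.934% at day 10. A larger small RNA share lowers the scaled values of the other genes in that library. How much of each turn with this scaling comes from it, and the causes of the other turns, were not tested.

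Leaving out one library at a time gave 12603 to 13118 genes at day 2, 13764 to 14091 at day 4, 13218 to 13990 at day 6, 13295 to 13975 at day 10, 11692 to 12137 at day 10 against day 2, 5607 to 8659 in RS, 10912 to 12364 for the difference and 9599 to 10171 with siDNMT1. Where an arm kept 1 library, it was assumed to vary like the other groups. The correlation of the siDNMT1 change with day 4 ran from -0.293 to -0.281 and with day 6 from -0.278 to -0.264. Over genes with a mean log2 of at least 2 it was -0.23 for day 4 and -0.229 for day 6.

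A replicate block gave 13060, 14073, 13803, 13859, 12446, 7314, 11555 and 10986 genes in the same order with siDNMT1 last, and 45 list tests. The 3 list calls past without the block and not with it lay in RS, with camera adjusted p = 0.0501 for CTCF, cohesin and condensin genes, 0.0509 for ERK targets and 0.0597 for cholesterol synthesis genes, and the last was also not past with scaling to total reads (0.0654). Deviations of same-numbered libraries correlated at -0.117 to 0.23 in OIS, -0.208 to 0.36 in RS and 0.107 in the siRNA libraries. Differing numbers gave -0.23 to 0.134 in OIS, -0.44 to 0.441 in RS and -0.107 in the siRNA libraries. The RS values gave no sign of pairing, and the OIS ranges overlapped. In groups of 2 libraries the deviations mirror each other, so the check cannot decide for the siRNA libraries. The labels do not say.

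Asking for overlap over 0.5 of the peak's length gave 50.0% (H3K4me3, RS), 23.7% and 37.1% (H3K9me3, OIS day 10 and RS) and 59.4% and 57.2% (H3K27me3, OIS day 10 and RS). The stricter 0.5 of each list gave 98.0% and 63.3% for H3K4me3, 26.8% and 46.6% for H3K9me3 and 48.2% and 58.7% for H3K27me3, in OIS day 10 and RS. Autosomes alone gave 42.4% for H3K9me3 and 65.9% for H3K27me3 in RS, and an FDR under 0.05 gave 62.1% for H3K27me3 at day 10. Expression by promoter peaks, with both of its alternatives, was not run.

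Of the 10 splits of the 6 libraries, 1 gave as many genes as the real grouping at day 2 (13076), at day 4 (14114) and in RS (7574), the real one itself, and the highest other split gave 0. With 10 splits a share under 0.05 cannot be reached.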

Other observations

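The median level of the interferon-stimulated genes was 0.798 FPKM at OIS day 0, 0.485 at day 2, 19.9 at day 4, 5.69 at day 6 and 1.08 at day 10. It was 0.442 in proliferative and 1.25 in senescent RS cells, 5.90 with siNT4 and 54.7 with siDNMT1. CXCL10, a chemokine gene under interferon control, stood at 23.8 FPKM at day 4 and 0.374 at day 10. Differences between the siNT4 libraries of day 5 and the time course at days 4 and 6 were not tested, since they come from separate experiments. There IL8 stood at 45.7 ± 1.95 (n = 2) against 1097 ± 216.2 (n = 3) and 3008 ± 38.5 (n = 2), and IL1B at 54.7 ± 3.10 against 1173 ± 130.0 and 2020 ± 26.9.

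Markers of other cell types were few. Among endothelial genes TIE1, a vessel receptor gene, rose by 4.34 at OIS day 4 and fell by 2.28 with siDNMT1, while its relative TEK fell by 2.30 at day 10 and rose by 0.80 in RS (4 genes tested at day 10, 3 up and 1 down, camera adjusted p = 0.316). Of epithelial keratins KRT18 fell by 1.52 and KRT19 rose by 1.39 in RS (4 genes tested, 1 up and 2 down, camera adjusted p = 0.328). Of germline genes the antigen genes PAGE5 (-2.48) and MAGEA12 (-0.67) fell at day 10, and the direction of MAGEA12 turned with scaling to total reads. HORMAD1, a meiotic gene, rose by 0.79 with siDNMT1. The neural gene SYP rose by 0.52 at day 10, SYT1 rose by 0.52 in RS and fell by 2.02 with siDNMT1, and the monocyte gene CD14 rose by 0.91 at day 10.

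Tests chosen after the result was seen were those of scaling, of the introduced genes' shares and of leukocyte markers. Those of germline genes, of siRNA delivery and of covered length were also chosen then. The correlation with day 2 and the gained-region tests were written before.

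The lower ERK targets with siDNMT1 may follow from less of the RAF1 fusion rather than from DNMT1 acting at those genes. Across genes the siDNMT1 change ran against the change at OIS day 2 with a Spearman correlation of -0.392, as this explanation predicted. The correlation was also negative with days 4 (-0.326), 6 (-0.274) and 10 (-0.255). A direct effect of DNMT1 on genes of the time course could give the same sign, so this test does not separate the 2. Scaling did not account for the fall of RAF1, whose smallest value over 3 scalings was -2.25. After subtraction of the primary cells' level, 8.99% of RAF1 and 9.86% of TERT was left, a difference of 0.863 points, which is compatible with a shared loss of both introduced genes. A direct effect of DNMT1 on ERK targets, an effect on the introduced genes' promoters and an effect of this siRNA outside DNMT1 stay open, since the fusion was not restored in any library.

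The rise of interferon-stimulated genes with siDNMT1 may have several sources. RNA from leukocytes was excluded by the marker test, with 0 markers at 0.5 FPKM or more and above siNT4 (CD14 at 0.197 and CSF1R at 0.152 FPKM were the highest). Loss of promoter methylation stays open, since 1 germline gene, HORMAD1, reached 0.919 FPKM against 0.112 with siNT4, where 5 were asked for. The siNT4 libraries also received an siRNA, and the median of these genes was 5.90 FPKM there against 54.7 with siDNMT1. These values argue against delivery alone as the source only if both siRNAs were delivered alike, which was not tested. A response to the sequence of this siRNA was not tested, since no siRNA against another gene was at hand. That 34 of 34 interferon genes were above siNT4 in both siDNMT1 libraries, where chance gives 16.7% of genes in that direction, is the observation itself and bears on no source. Repeat transcripts and DNA methylation were not analysed here.

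The overlap of H3K9me3 with H3K27me3 in senescent RS cells may reflect signal of one mark in the other's list. In these cells 44.4% of H3K9me3 length lay inside H3K27me3 regions, against at most 28.7% over the circular shifts. Covered length with random placement thus did not account for the overlap. The shifts place regions at random, so longer lists that grow at particular places stay open. Of the H3K9me3 length gained over proliferative cells, 64.4% lay in regions that already carried H3K27me3 there, against at most 20.6% over the shifts. Of the gained H3K27me3 length, 25.8% lay in earlier H3K9me3 regions, against at most 24.3%, so both directions of mixing met their prediction, the second narrowly. Most of the gained H3K9me3 therefore lay where H3K27me3 was already listed. A true gain of H3K9me3 on such regions stays open, as does spread between replicates, since each condition has 1 list.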
